A study of Homo sapiens with 11 samples.

How the data were processed

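Gene expression was measured on 11 Affymetrix oligonucleotide arrays of human material, each hybridised with biotinylated cRNA. The labels assign 4 arrays to chordoma tumours, 3 to notochord, 3 to the chordoma cell lines CH22 and UCH1, and 1 to fetal spinal tissue. Total RNA of the tumours came from freshly resected tissue and was extracted with Trizol. Notochord was collected by laser capture microdissection and its RNA was extracted with a kit for small amounts of material. The deposited values are probe set intensities on a linear scale, which the authors scaled so that the mean of each array, with 2% of values trimmed at each end, is 500. The labels name the R package affy, but its version, its settings and the summarization method are not given in the sources used here. Detection calls were not used here, so signal above background could not be tested for a single probe set. The number of arrays limits the precision of every comparison.

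The values were read in R 4.3.3. Array medians of the deposited intensities differed by 1.67 on the log2 scale, more than the 0.5 set before the data were examined as the limit for leaving the authors' scaling alone. Values were therefore transformed as log2(intensity + 16) and quantile normalized over the arrays. Adding 16 pulls weak signals together, so differences of weakly expressed genes are understated. Of 54675 probe sets, 42898 were in the probe table. Of these, 41097 named 1 gene, 1801 named several, and 11777 probe sets had no entry. Symbols of 41043 single-gene probe sets were updated through Entrez identifiers, and 54 were not matched. A further 59 probe sets of sex-linked genes were left out to protect donors. Each of the 19740 genes was represented by its probe set with the highest mean over all arrays. A gene was kept if that probe set lay above the 40th percentile of its array on at least 2 of the 10 arrays other than fetal spine, which left 16673 genes.

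The arrays were grouped into 8 units. Each tumour was a unit, the first 2 notochord arrays, whose titles share a specimen number, were averaged to specimen 1, the remaining notochord array was specimen 2, and arrays of the same cell line were averaged. The labels do not say whether 2 units share a donor. Tumours 2 and 3 resembled each other (rank correlation 0.962) more than the 2 arrays of notochord specimen 1 did (0.883), so they may not be independent, and counted as 1 replicate they left 53 of 285 calls between tumours and notochord and 518 of 1291 between cell lines and tumours. No paired analysis was possible because the labels do not link tumours, notochord specimens and cell lines. Tumours are numbered 1 to 4 in the order of deposition. A single limma 3.58.1 fit (lmFit, contrasts.fit, eBayes) over the 8 units, with 5 residual and 5.60 prior degrees of freedom, compared tumours with notochord, cell lines with tumours, and cell lines with notochord. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 16673 genes within a comparison, and an adjusted p under 0.05 was a call. Means and SDs in the text are over units on the log2 scale, and a difference of 1 is a 2-fold difference. The fetal spine array has no replicate and entered no test. Its difference from the mean of the 2 notochord specimens was placed, for each gene list, among 10000 random lists of the same size matched on mean expression.

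Before the data were examined, 34 gene lists were fixed: notochord identity, epithelial cytokeratin and junction, cartilage matrix, cell cycle, fibroblast, macrophage, T and NK cell, B and plasma cell, endothelial, erythroid, neutrophil and marrow, skeletal muscle, neural, osteoblast, osteoclast and adipocyte markers, MHC class 1, MHC class 2, interferon response, hypoxia and glycolysis, immediate early, receptor tyrosine kinases, hedgehog, TGF-beta and BMP, mesenchymal, posterior HOX, anterior and central HOX, ribosomal proteins, oxidative phosphorylation, unfolded protein response, lysosome, G1 checkpoint, genes known to be altered in chordoma, and cholesterol synthesis. Several of these overlap: KRT19, SHH and TBXT, for example, each stand in more than 1 list. Each list was tested with camera on the same fit, with a preset correlation between genes of 0.01 and adjustment over the 34 lists. The tests were repeated with a correlation estimated from the data and with fry, which tests whether the genes of a list move, on balance, one way. Members were also adjusted over the list alone.

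Genes named in the text follow a rule fixed before the data were examined. For tumours against notochord and for cell lines against tumours these were the 12 largest differences in each direction among called genes whose arrays did not overlap. For cell lines against notochord they were the 6 largest in each direction. From each list, up to 4 called members with the lowest adjusted p were added, or up to 2 with the lowest p where none was called. For fetal spine they were the 6 highest and 6 lowest differences among genes outside the range of the notochord arrays. TBXT was given in every group.

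The procedure was tested on simulated data in which 200 genes were changed in each of 20 draws. For tumours against notochord, 5.90% of 4-fold, 79.1% of 16-fold and 99.5% of 64-fold changes were called, and 4.86% of calls were false. The corresponding recovery was 4.30%, 79.5% and 98.9% for cell lines against tumours, with 5.84% false calls. It was 2.10%, 56.5% and 96.1% for cell lines against notochord, with 6.01% false calls. The list test called a list of 20 genes shifted by 2 on the log2 scale in 20 of 20 draws and 0 of 660 unshifted lists. Simulated genes were drawn independently of each other, so this gives no false call rate for lists whose genes vary together. Correlations estimated from the data ran from -0.0605 for B and plasma cell markers to 0.747 for MHC class 1 genes.

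Alternatives covered the scaling, the pseudocount, the filter, the choice of probe set, the treatment of arrays of one specimen or line, the fit, the set test, and leaving out each unit and each averaged array. The authors' scaling alone, median centring for the list tests, array weights and counting tumours 2 and 3 as 1 replicate were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.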

Results

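Chordoma is a malignant bone tumour of the axial skeleton, and the notochord is the embryonic midline rod from which it is thought to arise. Expression was compared among 4 resected chordomas, 2 notochord specimens (3 arrays), the chordoma cell lines CH22 (2 arrays) and UCH1 (1 array), and 1 fetal spinal tissue array. The mean intensity of every array, trimmed at both ends, was 500, and the median deposited intensity ran from 55.1 in CH22 to 210.7 on a notochord array. The 3'/5' signal ratio of beta-actin probe sets, which grows as RNA is shortened, was 15, 20.5 and 47.9 on the notochord arrays. It was 20.5 in tumour 1, between 5.35 and 8.19 in tumours 2 to 4, 5.08 in fetal spine, 2.59 and 2.55 in CH22 and 4.61 in UCH1. The GAPDH 3'/5' ratio set the notochord arrays less apart, at 2.31, 1.43 and 4.00 against 0.69 to 1.97 on all other arrays. The middle value lies within the range of the others. Rank correlations across the 16673 genes, which are not independent replicates, were 0.981 between the CH22 arrays and 0.962 between tumours 2 and 3. They ran from 0.637 to 0.962 among tumours, from 0.831 to 0.883 among notochord arrays and from 0.575 to 0.629 between cell lines and notochord. The first principal component held 35.8% of the variance and set the cell lines, at 120.3 to 157.6, apart from all other arrays, at -88.8 to -9.37. The second, with 18.3%, set the tumours, at 65.6 to 99.8, apart from notochord, at -75.4 to -61.9.

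**Figure D1:**
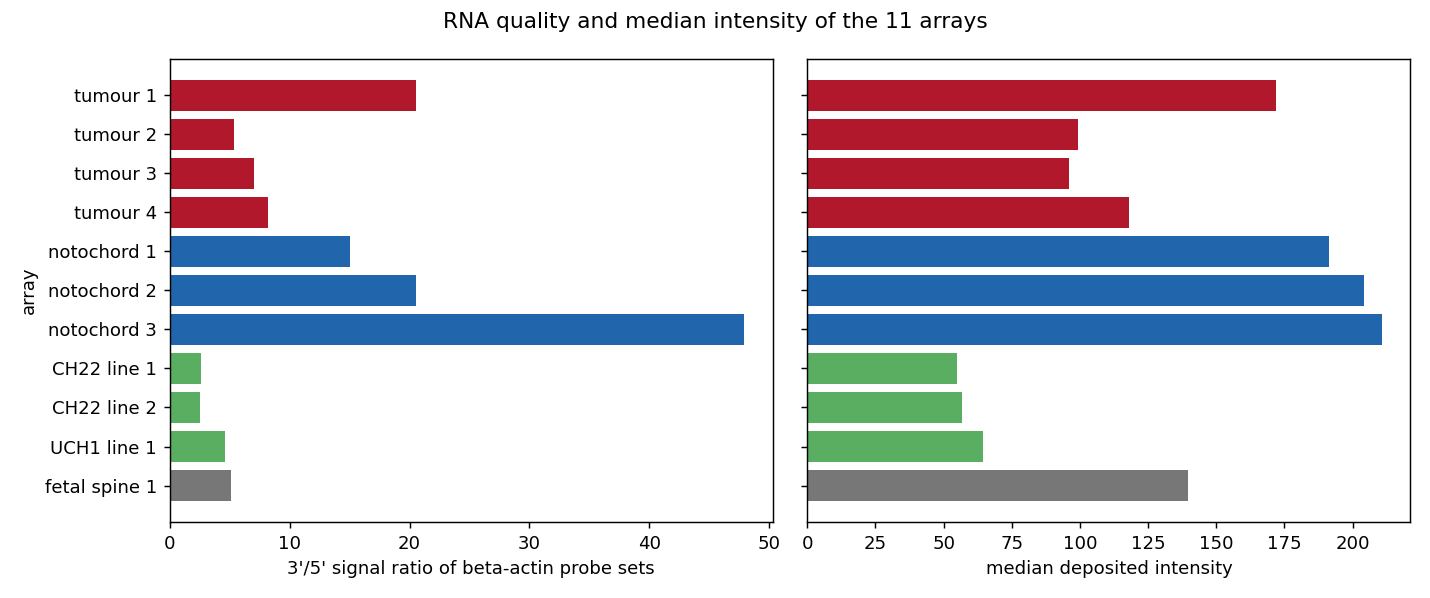
Bars, drawn from 0, give the beta-actin 3'/5' signal ratio and the median deposited intensity of each of the 11 arrays. The notochord arrays and tumour 1 have actin ratios of 15 to 47.9, above the 2.55 to 8.19 of all other arrays.

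TBXT, which encodes brachyury, the transcription factor that marks notochord and chordoma, was strongly expressed in all 3 classes and low in fetal spine. Its log2 intensity was 13.29 ± 0.53 in tumours (SD, n = 4), 13.55 ± 0.09 in notochord (SD, n = 2) and 13.99 ± 0.98 in cell lines (SD, n = 2), against 4.70 on the fetal spine array. Differences among the 3 classes were not called, with limma adjusted p-values of 0.873, 0.518 and 0.739. Over the 15 measured notochord identity genes the median difference between tumours and notochord was 0.20 (camera adjusted p = 0.904), but -0.11 under the authors' scaling. NOG, an inhibitor of bone morphogenetic proteins, was the 1 called member and was lower in tumours, at 5.94 ± 0.49 (SD, n = 4) against 9.01 ± 0.31 (SD, n = 2, adjusted p = 0.0354). The list had 1 lower member when adjusted over the list alone. NOG lost its call after median centring, with 1 added in place of 16 and with only the 2 classes fitted. It also lost its call without tumour 2, without tumour 3 and with tumours 2 and 3 as 1 replicate.

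The first comparison asked how chordoma tumours differ from notochord. By camera with a preset correlation, cartilage, muscle, marrow and bone lists were lower in tumours and MHC, macrophage and T and NK cell lists higher, in most of which a minority of members was called, and with an estimated correlation no list was called. DLK1, a regulator of progenitor differentiation, was 4.91 ± 0.46 in tumours (SD, n = 4) and 13.06 ± 0.17 in notochord (SD, n = 2), a log2 difference of -8.15 (SE 0.56, adjusted p = 0.000422). It was 13.62 on the fetal spine array, where TBXT was 4.70, so a high DLK1 value was not particular to notochord. HLA-DRA, a chain of MHC class 2 molecules, was 13.59 ± 0.96 in tumours and 7.52 ± 1.55 in notochord, a difference of 6.07 (SE 0.80, adjusted p = 0.0086). CCND1, a cyclin that drives G1 progression, was higher in tumours by 3.29 (SE 0.61, adjusted p = 0.0315), and the CDK inhibitor CDKN1A by 3.27 (SE 0.63, adjusted p = 0.0370).

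In all, 285 of 16673 genes were called, 123 higher and 162 lower in tumours, and 2882 had an unadjusted p under 0.05. With each specimen counted once, tumours and notochord did not overlap for all 285 called genes and for 27.6% of all genes, where chance gives 13.3%. The split depended on scaling: under the authors' scaling 42 were higher and 189 lower, and with arrays centred on their medians 93 were higher and 63 lower. The median difference over all genes was -0.01 after quantile normalization, -0.33 under the authors' scaling and 0.38 after median centring. The count was 1043 without tumour 1, 26 without tumour 2 and 50 without tumour 3. It was 15 without notochord specimen 1, 26 without specimen 2, and 53 when tumours 2 and 3 counted as 1 replicate. Of 57 called genes named by the rule, 6 (DLK1, MATN1, COL9A1, MPO, PANX3 and UCMA) stayed called whichever unit was left out. Of the 57, 12 lost their call under the authors' scaling, 22 after median centring, 26 with 1 added in place of 16 and 21 with only the 2 classes fitted. With the specimen or line as a random block 9 lost their call: APOD, CARD16, CD14, CD3G, CTSG, EMCN, MEPE, TIE1 and TYROBP. Capture and extraction differed between notochord and all other samples, so tissue and preparation cannot be told apart in this comparison.

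**Figure D2:**
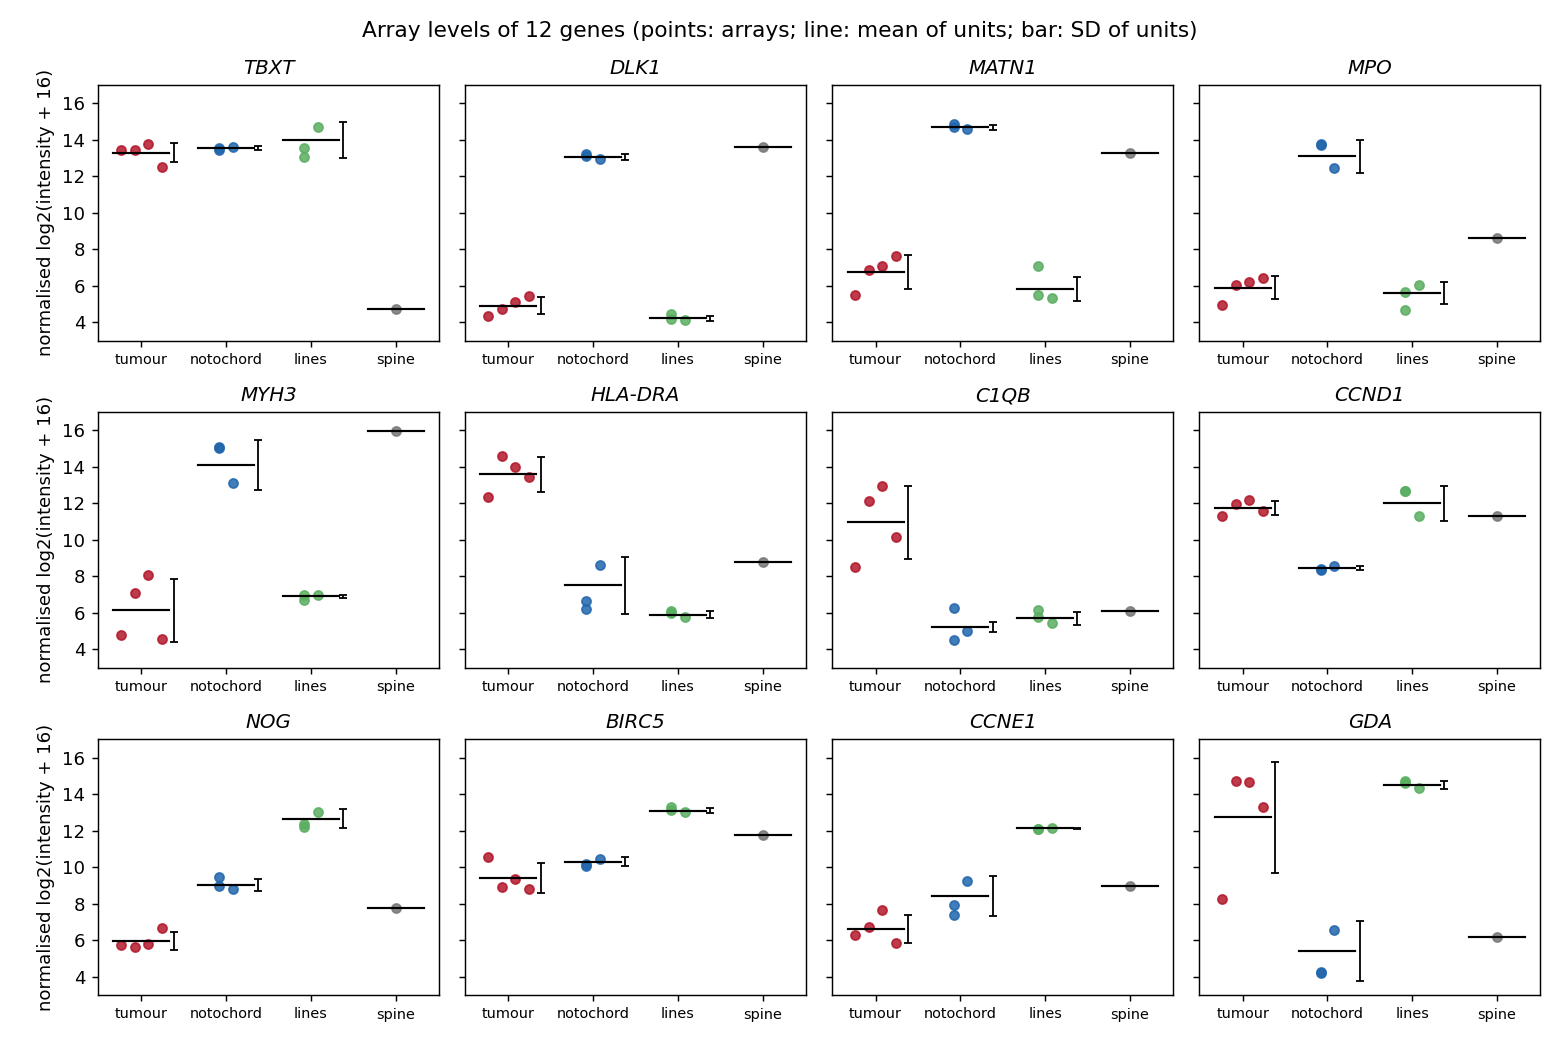
Points give the normalized log2 intensity of 12 genes on each array, the line the mean of the units of a class and the bar its SD. TBXT lies near 13.29 in tumours, 13.55 in notochord and 13.99 in cell lines, whereas DLK1 falls from 13.06 in notochord to 4.91 in tumours.

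Cartilage and bone genes were lower in tumours than in notochord. Of 25 measured cartilage matrix genes, 8 were lower, and 14 when adjusted over the list alone, with a median difference of -3.12 (camera adjusted p = 1.12e-10, adjusted p = 0.180 with an estimated correlation). MATN1, a cartilage matrilin, differed by -7.91 (SE 0.69), the collagen IX chain gene COL9A1 by -7.52 (SE 0.66), UCMA by -5.56 (SE 0.52) and MATN3 by -5.39 (SE 0.71). The MATN1 call was lost when probe sets that can match several transcripts were left out, as were those of EMCN, HOXB6 and GDA, which are described below. The collagenase MMP13, made by hypertrophic chondrocytes and bone cells, differed by -7.55 (SE 0.87, adjusted p = 0.0043) and the chondrocyte channel gene PANX3 by -6.75 (SE 0.73, adjusted p = 0.0037). Among 8 osteoblast markers, 5 were lower and 7 when adjusted over the list alone, with a median of -3.02 (camera adjusted p = 1.41e-08, adjusted p = 0.16 with an estimated correlation). They included IBSP, a bone matrix protein gene, at -7.01 (SE 0.89), and SP7, MEPE and ALPL. Of 5 osteoclast markers, CTSK alone was called, at -3.82 (SE 0.75), and 2 were lower when adjusted over the list alone. Their median was -2.22 (camera adjusted p = 0.0030, adjusted p = 0.180 with an estimated correlation). CTSK, SP7, MEPE and ALPL lost their call after median centring, with 1 added before the log2 step and with only the 2 classes fitted. CTSK also lost its call under the authors' scaling.

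Muscle and marrow genes were also lower in tumours. Of 18 skeletal muscle markers 5 were lower, and 14 when adjusted over the list alone, with a median of -4.24 (camera adjusted p = 8.99e-12, adjusted p = 0.203 with an estimated correlation). The embryonic myosin MYH3 differed by -7.96 (SE 1.02), MYH8 by -6.76 (SE 1.00), MYH2 by -5.90 (SE 0.83) and titin, TTN, by -5.26 (SE 0.78). The myosin light chain MYL1 differed by -7.09 (SE 1.30) and SLN, a regulator of the muscle calcium pump, by -6.97 (SE 0.76). Mean log2 intensity of the muscle list was 11.65 and 11.58 on the arrays of notochord specimen 1, 8.74 in specimen 2, 12.84 in fetal spine and 5.38 to 7.96 in tumours. Of 10 neutrophil and marrow markers 5 were lower, and 9 when adjusted over the list alone, with a median of -3.78 (camera adjusted p = 1.88e-11, adjusted p = 0.180 with an estimated correlation). The granule genes MPO, at -7.20 (SE 0.67), S100A12, at -6.15 (SE 0.65), DEFA4 and CTSG were among them, and the marrow gene MS4A3 differed by -6.88 (SE 0.88). Of 5 erythroid markers 3 were lower (AHSP, HEMGN and SLC4A1), and 4 when adjusted over the list alone. Their median was -3.86 (camera adjusted p = 0.000202, adjusted p = 0.203 with an estimated correlation). The globin gene HBB went the other way, at 1.19, and was not called. It was 15.67 and 15.14 in tumours 1 and 4, 8.98 and 9.93 in tumours 2 and 3, and 10.12 to 12.17 on the notochord arrays.

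Vessel, stromal and patterning lists were lower in tumours by smaller amounts. Of 13 endothelial markers TIE1, at -2.83 (SE 0.56), and EMCN, at -2.71 (SE 0.58), were called, and 6 were lower when adjusted over the list alone. Their median was -2.05 (camera adjusted p = 0.000233, adjusted p = 0.180 with an estimated correlation). TIE1 and EMCN both lost their call after median centring, with the specimen or line as a random block and with only the 2 classes fitted. The fibroblast list, with COL5A2 called at -3.50 (SE 0.66) among 17 members, had a median of -1.18 (camera adjusted p = 0.0089, adjusted p = 0.203 with an estimated correlation). When adjusted over the list alone 3 were lower and 1 higher. None of 13 mesenchymal genes was called, 0 when adjusted over the list alone, with a median of -1.04 (camera adjusted p = 0.0252, adjusted p = 0.203 with an estimated correlation). The fibroblast call was lost without notochord specimen 1, and the mesenchymal call without that specimen, without tumour 3 and under both other scalings. HOXD4, at -4.25 (SE 0.71), and HOXB6, at -2.59 (SE 0.55), were called among 15 anterior and central HOX genes, 2 when adjusted over the list alone. That list had a median of -1.16 (camera adjusted p = 0.0046, adjusted p = 0.180 with an estimated correlation). COL5A2 and HOXB6 lost their call under the authors' scaling and after median centring. Both also lost it with 1 added before the log2 step and with only the 2 classes fitted.

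Growth factor receptors went both ways. Of 22 receptor tyrosine kinases FGFR3 differed by -5.68 (SE 1.05), EPHB4 by -4.36 (SE 0.92) and FGFR2 by 3.65 (SE 0.66). FGFR2 rests on 1 probe set, and the mean of its probe sets gave -0.87. When adjusted over the list alone 3 were lower and 1 higher, and the median was -0.83 (camera adjusted p = 0.0118, adjusted p = 0.180 with an estimated correlation). This list call was lost without notochord specimen 2 and under the authors' scaling. FGFR3 and EPHB4 lost their call after median centring and with 1 added before the log2 step. EPHB4 also lost its call with only the 2 classes fitted. FGFR2 lost its call under the authors' scaling and with 1 added before the log2 step. Among 33 cell cycle genes only the kinetochore gene CENPF was called, at -4.44 (SE 0.61), and 2 were lower when adjusted over the list alone. Their median was -1.48 (camera adjusted p = 1.87e-08, adjusted p = 0.203 with an estimated correlation).

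Macrophage, T and NK cell, MHC and interferon lists were higher in tumours than in notochord, unlike the marrow list, which was lower, and the B and plasma cell list, which was not called. Of 15 macrophage markers all had a positive difference, 3 were called higher and 7 when adjusted over the list alone, with a median of 2.47 (camera adjusted p = 1.25e-06, adjusted p = 0.270 with an estimated correlation). Called members were the complement gene C1QB, at 5.74 (SE 1.06), the adaptor TYROBP, at 4.08 (SE 0.73), and the endotoxin co-receptor CD14, at 3.67 (SE 0.77). Of 11 T and NK cell markers 3 were higher, and 8 when adjusted over the list alone, with a median of 3.41 (camera adjusted p = 2.5e-07, adjusted p = 0.211 with an estimated correlation). They were the chemokine CCL5, at 6.09 (SE 1.01), and the T cell receptor components CD3E, at 4.00 (SE 0.81), and CD3G, at 3.65 (SE 0.75). CCL5 was also 7.76 and 7.47 in CH22 and 9.72 in UCH1, which hold no immune cells, against 4.82 to 6.69 on the notochord arrays. HLA-DRA and HLA-DPA1 were higher among 8 MHC class 2 genes, and 4 when adjusted over the list alone, with a median of 3.05 (camera adjusted p = 3.45e-06, adjusted p = 0.203 with an estimated correlation). No single member was called among 12 MHC class 1 genes or 16 interferon response genes, and 4 of each when adjusted over the list alone. Their medians were 2.14 (camera adjusted p = 8.72e-06, adjusted p = 0.275 with an estimated correlation) and 2.64 (camera adjusted p = 5.66e-07, adjusted p = 0.270 with an estimated correlation). Of these 8 called genes, CD14, CD3G and HLA-DPA1 lost their call under the authors' scaling and after median centring. TYROBP, CD14 and CD3G lost it with the specimen or line as a random block, and C1QB, CD3E, CD14 and CD3G with only the 2 classes fitted. Only HLA-DRA stayed called without tumour 2, without tumour 3, without notochord specimen 2 or with tumours 2 and 3 as 1 replicate. None of the 8 stayed called without notochord specimen 1, and 5 did without tumour 4. Mean log2 intensity of the macrophage list was 8.72 in tumour 1, whose actin ratio was 20.5, 11.62 in tumour 2, 11.89 in tumour 3, 9.89 in tumour 4, 7.85 to 8.30 on notochord arrays and 7.32 in fetal spine.

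Other genes higher in tumours were GDA, a guanine deaminase, at 7.33 (SE 1.56, adjusted p = 0.0479), the caspase-1 regulator CARD16 at 6.23 (SE 1.09) and the lipocalin APOD at 5.37 (SE 0.99). The GDA call lay close to the threshold. It was lost under the authors' scaling, after median centring, with 1 or 64 added in place of 16, without the filter, with only the 2 classes fitted and with the mean of its probe sets, and its difference was 1.54 without probe sets that can match several transcripts. GDA was 8.27 in tumour 1 and at least 13.29 in the other tumours. HPGDS, a prostaglandin D synthase, differed by 5.31 (SE 0.82), EGFLAM by 5.27 (SE 0.89), CCL18, a chemokine of macrophages, by 5.24 (SE 0.84) and ERAP2, which trims peptides for antigen presentation, by 5.03 (SE 0.82). SLC46A3 differed by 4.98 (SE 0.87), the complement gene C3 by 4.95 (SE 1.07) and KRT15, a cytokeratin, by 2.93 (SE 0.57). CARD16 and APOD lost their call with the specimen or line as a random block, and APOD, SLC46A3, C3 and KRT15 under the authors' scaling. The C3 call was also lost after median centring, with 1 or 64 added in place of 16, without the filter and with only the 2 classes fitted. No member of the 25 oxidative phosphorylation genes was called and 1 was higher when adjusted over the list alone, with a median of 0.80 (camera adjusted p = 0.000262, adjusted p = 0.203 with an estimated correlation). The 17 lysosome genes had no called member and 2 higher when adjusted over the list alone, with a median of 1.06 (camera adjusted p = 0.0038, adjusted p = 0.275 with an estimated correlation). All 19 called lists kept the sign of their median under the authors' scaling and median centring, but the sizes changed. After median centring the fibroblast, mesenchymal and receptor tyrosine kinase medians were only -0.36, -0.25 and -0.35, while those of lists higher in tumours grew.

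The other 15 lists were not called between tumours and notochord. Their medians were 0.44 for cytokeratin and junction genes (-0.01 under the authors' scaling), -0.33 for B and plasma cell markers, -0.74 for neural markers, 0.25 for adipocyte markers and -0.11 for hypoxia and glycolysis (0.05 under the authors' scaling and 0.76 after median centring). Immediate early genes had a median of 0.40, hedgehog genes -0.99, TGF-beta and BMP genes -0.49, posterior HOX genes -0.29 and ribosomal proteins 0.12. The unfolded protein response gave -0.06 (0.70 after median centring), G1 checkpoint genes 0.64, genes altered in chordoma -0.77 and cholesterol synthesis -0.51. Their camera adjusted p-values ran from 0.0585 to 0.965, and the signs of median, mean and test differed in 2 of them. BOC, a hedgehog co-receptor, was called at -3.31 (SE 0.54, adjusted p = 0.0208). When adjusted over the list alone the members past the threshold were 1 lower neural, chordoma and cholesterol gene each, 1 higher B cell and cytokeratin gene each, 2 higher immediate early and G1 genes each, 2 lower hedgehog genes, and 2 higher and 1 lower posterior HOX genes.

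**Figure D3:**
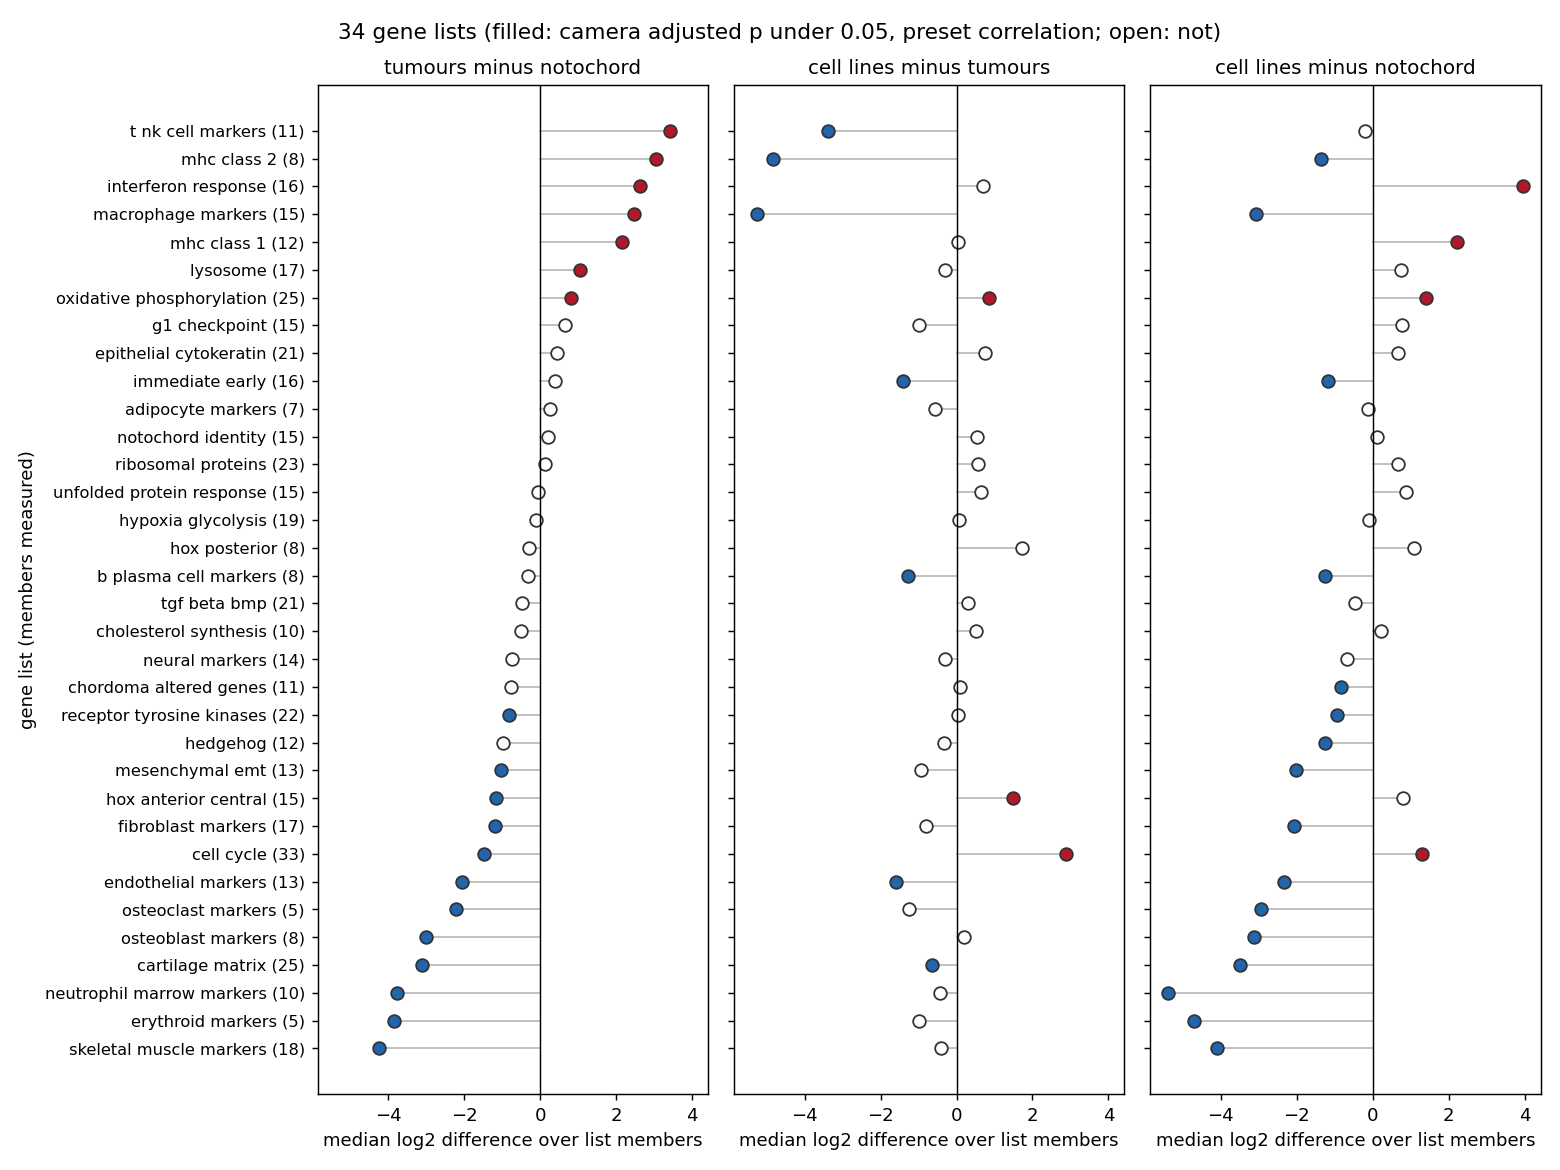
Points give the median log2 difference of each of the 34 gene lists in the 3 comparisons, filled where the camera adjusted p was under 0.05. Skeletal muscle markers lie at -4.24 and T and NK cell markers at 3.41 for tumours against notochord, and signs of the unfilled medians near 0 depend on scaling, as do those of 2 filled lists, immediate early and chordoma-altered genes, for cell lines against notochord.

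The second comparison asked how the cell lines differ from the tumours they model. By camera with a preset correlation, macrophage, T and NK cell and MHC class 2 lists were lower in the lines, with 14 of 15, 5 of 11 and 6 of 8 members called, and the cell cycle list was higher, with 18 of 33. None of these lists was called with an estimated correlation (adjusted p = 0.226, 0.309, 0.226 and 0.226). The macrophage scavenger receptor CD163 was 5.05 ± 0.58 in lines (SD, n = 2) and 12.11 ± 1.40 in tumours (SD, n = 4), a difference of -7.06 (SE 0.89, adjusted p = 0.0051). CCNE1, the cyclin that starts S phase, was 12.12 ± 0.04 in lines and 6.63 ± 0.77 in tumours, a difference of 5.49 (SE 0.69, adjusted p = 0.0051). NOG was higher in lines by 6.71 (SE 0.59, adjusted p = 0.0029), although TBXT was not called.

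Calls were made for 1291 genes, 721 higher and 570 lower in lines, and 4398 had an unadjusted p under 0.05. Under the authors' scaling 909 were higher and 1037 lower, and after median centring 2498 were higher and 541 lower. The median difference over all genes was 0.26, -0.10 and 0.72 under the 3 scalings. The count was 28 without CH22, 276 without UCH1, 2144 without tumour 1, 350 without tumour 2 and 658 without tumour 3. Of 85 called genes named by the rule, 11 stayed called whichever unit was left out: DLX2, NOG, NEIL3, ADAMTS3, HLA-DRA, CD74, CXCR4, ALOX5AP, TENT5C, DCN and TYROBP.

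Of 15 macrophage markers 14 were lower in lines, and 15 when adjusted over the list alone, with a median of -5.26 (camera adjusted p = 4.89e-16, adjusted p = 0.226 with an estimated correlation). AIF1 differed by -7.18 (SE 1.18), the growth factor receptor CSF1R by -5.99 (SE 0.87) and TYROBP by -5.95 (SE 0.73). Of 8 MHC class 2 genes 6 were lower, and 7 when adjusted over the list alone, with a median of -4.83 (camera adjusted p = 1.23e-08, adjusted p = 0.226 with an estimated correlation). HLA-DRA differed by -7.68 (SE 0.80), the invariant chain CD74 by -7.42 (SE 1.01) and the transactivator CIITA by -5.46 (SE 0.74). T and NK cell markers were lower for 5 of 11, and 8 when adjusted over the list alone, with a median of -3.38 (camera adjusted p = 5.08e-07, adjusted p = 0.309 with an estimated correlation). GZMA, a granzyme, differed by -6.06 (SE 0.96). Of 8 B and plasma cell markers IGKC was called, at -2.38 (SE 0.61), and 3 when adjusted over the list alone, with a median of -1.27 (camera adjusted p = 0.0058, adjusted p = 0.226 with an estimated correlation). Endothelial markers were lower for 4 of 13, with PECAM1 at -5.87 (SE 0.74), and 5 when adjusted over the list alone. Their median was -1.60 (camera adjusted p = 0.0203, adjusted p = 0.295 with an estimated correlation), a call lost without UCH1. Myeloid and lymphoid genes outside the lists included lysozyme, LYZ, at -8.32 (SE 1.00), ARHGDIB at -7.19 (SE 0.98), the chemokine receptor CXCR4 at -6.57 (SE 0.90) and ALOX5AP at -6.16 (SE 0.66).

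Cell cycle genes were higher in lines for 18 of 33, and 27 when adjusted over the list alone, with a median of 2.89 (camera adjusted p = 1.84e-12, adjusted p = 0.226 with an estimated correlation). CCNB1, the mitotic cyclin, differed by 4.11 (SE 0.59), the ribonucleotide reductase gene RRM2 by 3.68 (SE 0.63) and survivin, BIRC5, by 3.68 (SE 0.64). Other mitotic and repair genes among the largest differences were NEIL3 at 6.35 (SE 0.68), KIF18B at 5.94 (SE 0.94), CDCA8 at 5.59 (SE 0.69) and TRIP13 at 5.44 (SE 0.62). The G1 cyclin CCND2 differed by -4.63 (SE 0.73), and the CDK inhibitor gene CDKN2B differed by -3.09 (SE 0.73). Oxidative phosphorylation genes were higher for 4 of 25, and 5 when adjusted over the list alone, with a median of 0.86 (camera adjusted p = 0.0058, adjusted p = 0.309 with an estimated correlation). Anterior and central HOX genes were higher for 3 of 15, HOXC4, HOXC6 and HOXB7, and 7 when adjusted over the list alone. Their median was 1.49 (camera adjusted p = 0.0054, adjusted p = 0.226 with an estimated correlation). HOXC6 lost its call with the specimen or line as a random block.

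Immediate early genes were lower in lines for 5 of 16, and 8 when adjusted over the list alone, with a median of -1.41 (camera adjusted p = 1.01e-05, adjusted p = 0.265 with an estimated correlation). EGR1 differed by -4.61 (SE 0.83), FOS by -4.35 (SE 0.85) and ZFP36 by -4.14 (SE 0.59). Cartilage genes went both ways: SOX6, COL2A1 and COL11A1 differed by -4.41 (SE 0.78), -4.43 (SE 1.03) and -3.83 (SE 0.97), and the link protein HAPLN1 by 5.23 (SE 1.26). With 4 lower and 1 higher of 25, the same counts when adjusted over the list alone, the median was -0.66 (camera adjusted p = 0.0447, adjusted p = 0.622 with an estimated correlation). That call was lost without tumour 1, without tumour 4 and without CH22. The TGF-beta and BMP list was not called, yet the BMP target genes ID1 and ID3 were higher by 5.43 (SE 0.70) and 4.83 (SE 0.65), and CCN2 and TGFBR2 differed by -3.89 (SE 0.60) and -4.05 (SE 0.75). Other large differences were the homeobox gene DLX2 at 6.77 (SE 0.73), the cadherin CDH10 at 6.26 (SE 0.84), TSPAN12 at 5.71 (SE 1.21), ADAMTS3 at 5.66 (SE 0.56) and CPA4 at 5.47 (SE 0.71). AEBP1, MUC6, APBB1IP and TENT5C differed by -7.30 (SE 1.06), -6.20 (SE 0.81), -6.26 (SE 0.75) and -6.15 (SE 0.55). The other 24 lists were not called, with medians from -1.24 to 1.71 and camera adjusted p-values from 0.0772 to 0.880. In 8 of them median, mean and test differed in sign.

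The third comparison set the cell lines, which hold no stroma, against notochord. By camera with a preset correlation, cartilage, marrow, muscle and bone lists were lower in lines, as they were in tumours. Interferon response and oxidative phosphorylation lists were higher, with 4 of 16 and 7 of 25 members called. None of these lists was called with an estimated correlation (adjusted p from 0.159 to 0.382). DLK1 was 4.23 ± 0.13 in lines (SD, n = 2) and 13.06 ± 0.17 in notochord (SD, n = 2), a difference of -8.83 (SE 0.65, adjusted p = 0.000798). NQO1, a quinone reductase, was 13.07 ± 0.50 in lines and 5.69 ± 0.03 in notochord, a difference of 7.38 (SE 0.74, adjusted p = 0.0024).

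Calls were made for 1561 genes, 887 higher and 674 lower in lines, and 4662 had an unadjusted p under 0.05. Under the authors' scaling 710 were higher and 1576 lower, and after median centring 3862 were higher and 454 lower. The median difference over all genes was 0.24, -0.38 and 1.16 under the 3 scalings. The count was 122 without CH22, 341 without UCH1, 241 without notochord specimen 1 and 84 without specimen 2. Of 92 called genes named by the rule, 18 stayed called whichever unit was left out, among them NQO1, DLX2, DLK1, LYZ, IBSP, COL9A1, MPO and CCND2.

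Cartilage genes were lower in lines for 13 of 25, and 17 when adjusted over the list alone, with a median of -3.50 (camera adjusted p = 1.88e-11, adjusted p = 0.159 with an estimated correlation). Marrow genes were lower for 8 of 10, and 8 when adjusted over the list alone, with a median of -5.40 (camera adjusted p = 5.96e-09, adjusted p = 0.159 with an estimated correlation). For muscle genes these counts were 7 of 18, and 13 when adjusted over the list alone, with a median of -4.11 (camera adjusted p = 5.57e-08, adjusted p = 0.263 with an estimated correlation). MATN1 differed by -8.86 (SE 0.80), IBSP by -8.12 (SE 1.03), S100A8 by -7.61 (SE 0.97), MPO by -7.49 (SE 0.77) and MYH8 by -7.37 (SE 1.15). MATN1 again lost its call without probe sets that can match several transcripts. Erythroid genes were lower for 4 of 5, and 5 when adjusted over the list alone, with a median of -4.70 (camera adjusted p = 0.000123, adjusted p = 0.225 with an estimated correlation). Osteoblast genes were lower for 5 of 8, and 7 when adjusted over the list alone, with a median of -3.14 (camera adjusted p = 6.93e-06, adjusted p = 0.159 with an estimated correlation). Osteoclast genes were lower for 2 of 5, and 4 when adjusted over the list alone, with a median of -2.93 (camera adjusted p = 0.0017, adjusted p = 0.159 with an estimated correlation). The notochord arrays carried muscle and marrow signal in both specimens, and their actin ratios of 15 to 47.9 exceeded the 2.55 to 4.61 of the lines.

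Endothelial, macrophage, B cell, MHC class 2, fibroblast and mesenchymal lists were lower in lines too, whereas T and NK cell markers were not called, with a median of -0.19 (camera adjusted p = 0.470) that was 0.09 after median centring. Endothelial genes were lower for 3 of 13, and 8 when adjusted over the list alone, with a median of -2.34 (camera adjusted p = 2.72e-06, adjusted p = 0.159 with an estimated correlation). Macrophage genes were lower for 2 of 15, CSF1R and LAPTM5, and 8 when adjusted over the list alone, with a median of -3.07 (camera adjusted p = 6.93e-06, adjusted p = 0.293 with an estimated correlation). B and plasma cell genes were lower for 2 of 8, and 3 when adjusted over the list alone, with a median of -1.26 (camera adjusted p = 0.0199, adjusted p = 0.173 with an estimated correlation). The called members, MS4A1 and POU2AF1, both lost their call with the specimen or line as a random block. Of 8 MHC class 2 genes CIITA and CD74 were lower, 2 when adjusted over the list alone, with a median of -1.37 (camera adjusted p = 0.0409, adjusted p = 0.442 with an estimated correlation). Fibroblast genes had 4 lower, such as DCN at -6.96 (SE 0.65), and THY1 higher among 17, or 6 and 1 when adjusted over the list alone. Their median was -2.09 (camera adjusted p = 0.0040, adjusted p = 0.209 with an estimated correlation). Mesenchymal genes had 4 lower of 13, and 6 lower and 1 higher when adjusted over the list alone, with a median of -2.03 (camera adjusted p = 0.0086, adjusted p = 0.173 with an estimated correlation). The B cell call was lost without notochord specimen 2, and the MHC class 2 call without that specimen and without CH22.

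Immediate early, receptor tyrosine kinase, hedgehog and chordoma-altered lists were lower in lines, and the TGF-beta and BMP list was not called, with a median of -0.47 (camera adjusted p = 0.120) that was 0.32 after median centring. Immediate early genes were lower for 5 of 16, and 6 when adjusted over the list alone, with a median of -1.18 (camera adjusted p = 0.0035, adjusted p = 0.273 with an estimated correlation) but 0.03 after median centring. Receptor tyrosine kinases had KDR, DDR2 and IGF1R lower and FGFR2 higher of 22, or 4 and 1 when adjusted over the list alone, with a median of -0.95 (camera adjusted p = 0.0165, adjusted p = 0.159 with an estimated correlation). FGFR2 differed by 4.58 (SE 0.76), but the mean of its probe sets gave -2.03. Hedgehog genes had BOC, HHIP and PTCH1 lower and the ligand SHH higher of 12, or 3 and 2 when adjusted over the list alone. BOC, PTCH1 and SHH lost their call with the mean of their probe sets, and SHH also with only the 2 classes fitted. The median of the hedgehog list was -1.25 (camera adjusted p = 0.0347, adjusted p = 0.263 with an estimated correlation). Of 11 genes altered in chordoma LYST was lower, at -5.39 (SE 0.83), 1 when adjusted over the list alone. LYST lost its call without probe sets that can match several transcripts. The list had a median of -0.84 (camera adjusted p = 0.0385, adjusted p = 0.263 with an estimated correlation) but 0.08 after median centring. Of these calls, the chordoma-altered and hedgehog ones were lost without CH22, the chordoma-altered and receptor ones without notochord specimen 2, and the hedgehog one without specimen 1. All 4, immediate early genes included, were lost under the authors' scaling, and the chordoma-altered one also after median centring. The receptor and hedgehog medians were -0.05 and -0.26 after median centring.

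Genes higher in lines than in notochord included interferon targets. Of 16 interferon response genes 4 were higher, and 8 when adjusted over the list alone, with a median of 3.95 (camera adjusted p = 0.000201, adjusted p = 0.382 with an estimated correlation). ISG15 differed by 6.87 (SE 0.92), MX1 by 6.04 (SE 1.19) and IFIT3 by 5.25 (SE 1.21). MHC class 1 genes were higher for 2 of 12, PSMB8 and PSMB10, and 7 when adjusted over the list alone. Their median was 2.22 (camera adjusted p = 0.0036, adjusted p = 0.442 with an estimated correlation), a call lost without UCH1. PSMB10 lost its call with the specimen or line as a random block. Oxidative phosphorylation genes were higher for 7 of 25, and 12 when adjusted over the list alone, with a median of 1.41 (camera adjusted p = 2.72e-06, adjusted p = 0.159 with an estimated correlation). COX8A differed by 5.19 (SE 0.99) and UQCRC1 by 4.73 (SE 0.78). CCNB1 and BIRC5 were higher among 33 cell cycle genes, 1 when adjusted over the list alone. CCNB1 lost its call without probe sets that can match several transcripts, and BIRC5 with 1 added in place of 16. The median of the cell cycle list was 1.30 (camera adjusted p = 0.0086, adjusted p = 0.442 with an estimated correlation), a call lost without CH22. GDA differed by 9.10 (SE 1.80), DLX2 by 7.13 (SE 0.84), NOCT by 7.07 (SE 0.93) and LAMP3 by 6.86 (SE 1.65), and CCND1 by 3.52 (SE 0.70). MIR142 was among the largest differences in the other direction, but its value is not given because the probe set was matched to the microRNA by symbol alone. The other 14 lists were not called, with medians from -0.69 to 1.09 and camera adjusted p-values from 0.0716 to 0.959. In 2 of them median, mean and test differed in sign.

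None of the list calls in the 3 comparisons, 19, 10 and 20 of 34, was made with an estimated correlation, where 7, 6 and 9 of 34 lists had an unadjusted p under 0.05. With fry 14, 11 and 15 lists were called, which kept 13 of the 19, 8 of the 10 and 14 of the 20. Between tumours and notochord the calls lost with fry were the macrophage, T and NK cell, MHC class 1, interferon, mesenchymal and lysosome lists. Between cell lines and tumours they were the T and NK cell and cartilage lists. Between cell lines and notochord they were the interferon, MHC class 1, MHC class 2, skeletal muscle, macrophage and cell cycle lists.

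Genes called against notochord were compared between tumours and cell lines. Of the called genes, 57 were higher in both and 118 lower in both, and 1 was called in opposite directions. Independent lists of these sizes would share 6.54, 6.55 and 13.6 genes, but the comparisons are not independent, since both use the same notochord specimens. In 100 simulations with these specimens but without true differences, on average 0 and 0.01 genes were called higher or lower in both, a value that leaves out the differences themselves and so sets no level for the counts. The covariance across genes of the log2 differences was 1.35, against 0.414 on average and at most 0.431 in the simulations. The correlation was 0.558 against 0.577, and only the covariance can be compared. Simulated genes were drawn independently of each other, whereas measured genes vary together. The simulated ranges of the covariance, here and below, are therefore too narrow to set a level for chance. With 1 specimen in each comparison, so that no array was shared, the covariance was 1.00 and 1.02 in the 2 ways to divide them, against at most 0.0293 in simulations. The genes called in both were then 13 and 8 lower and 0 higher, from far fewer calls, where independent lists would share 0.154 and 0.0504 lower. Both specimens were captured in the same way and may share surrounding tissue, so this does not tell what in the notochord arrays sets them apart. Shared lower genes included DLK1, COL9A1 and BOC, and shared higher genes included CCND1. On the fetal spine array DLK1 was 13.62, COL9A1 10.79 and BOC 12.34, so these genes were not high in notochord alone. Shared counts were 1 higher and 11 lower without notochord specimen 1, 0 and 21 without specimen 2, 264 and 333 without tumour 1, 0 and 24 without tumour 2, 1 and 39 without tumour 3, and 41 and 102 without tumour 4. They were 4 and 31 without CH22, 8 and 48 without UCH1, and 2 and 40 with tumours 2 and 3 as 1 replicate.

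The fetal spine array was also set against notochord. It has no replicate and no test was made. TBXT differed by -8.85 from the notochord mean, LYST by -8.66, the folate receptor gene FOLR1 by -7.52, LGR6 by -7.30, YIF1B by -7.23 and the chloride channel gene CFTR by -7.16. Highest in fetal spine were PDLIM3 by 6.48, the neurofilament gene NEFL by 6.45, C8orf88 by 6.20, the neuronal migration gene DCX by 6.19, UCHL1 by 6.11 and CNTNAP2 by 6.09. The notochord identity list had a median of -1.48, at the 0.02 percentile of random lists, and cartilage genes -2.04, at percentile 0. Marrow genes had a median of -4.58, osteoblast genes -3.36 and hypoxia and glycolysis genes -1.67, each at percentile 0. Skeletal muscle genes, at 2.63, and neural genes, at 4.05, lay at percentile 100. Of the genes called higher in tumours, 64 of 123 (52%) lay on the notochord side in fetal spine, as did 94 of the 162 called lower (58%). Over all genes with a difference in these directions the shares were 48.6% and 45.7%, and the gap was not tested.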

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

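The RNA quality test of tumour 1 was chosen after its result was seen, and the test of a lower share of tumour cells before. Over the 4 tumours, 216 measures were examined for a sample whose gap to its nearest neighbour, divided by the whole range, exceeded Dixon's 95% critical value. This held for 13, namely 3 of 9 array quality measures, 1 of 34 list means and 9 of 173 named genes, and chance gives about 1 in 20.

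Tumour 1 stood apart in 6 of them. Its signal for the spiked BioB transcript was 24122 against at most 6248 in the other tumours (gap share 0.835), for the spiked cre transcript 536730 against at most 95779 (0.935), and for 18S ribosomal RNA 102060 against at most 20093 (0.889). On the notochord arrays these signals were high too, at 21834 to 33694, 269401 to 451328 and 160596 to 286510. Its mean over the fibroblast markers was 10.70 against at most 10.09 (0.953). HLA-DPA1 was 11.19 in tumour 1 and at least 13.41 in the others (0.838), and SLC46A3 was 9.25 against at least 10.56 (0.866). In tumour 1, 3754 genes lay over 2 (log2) from the mean of the other tumours. Medians over cell type markers moved apart in that tumour: macrophage markers differed by -2.54, T and NK cell markers by -1.87 and MHC class 2 genes by -2.03 from the other tumours, whereas fibroblast markers differed by 1.03, skeletal muscle markers by 2.28 and erythroid markers by 2.36. The test of a lower share of tumour cells took a clear fall in markers of other cell types as evidence against it. The lowest of the medians over fibroblast, macrophage, endothelial and T cell markers was -2.54. This cannot exclude a lower share, because some cell types can rise while others fall, and the endothelial median was 0.59. The notochord identity and cytokeratin medians, which a lower share would reduce, were 0.21 and 0.91 and so did not fall. Low RNA quality remains open too. The actin 3'/5' ratio of tumour 1 was 2.50 times the highest of the other tumours and, like its spiked signals, near the notochord arrays. Its ribosomal signals and its ratio of 3' to middle actin probe sets, 6.12, lay between the other tumours and the notochord arrays. Its GAPDH 3'/5' ratio, 1.51, lay within the other tumours, at 0.79 to 1.97. Its deviation across genes correlated by only 0.0675 with that of the notochord arrays from fetal spine, which also differ in capture. The composition of this tumour is a biological explanation that was not tested, and it cannot be told apart from RNA quality in a single array.

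Tumour 4 stood apart in 5 genes. It was lower for ATF3, at 8.32 against at least 9.85 in the other tumours (0.857), C3, at 7.37 against at least 11.13 (0.872), and EGFLAM, at 8.89 against at least 11.84 (0.934). It was higher for ID1, at 6.49 against at most 4.86 (0.830), and RPS14, at 15.15 against at most 14.22 (0.937). Tumour 3 was higher for LSS, at 8.37 against at most 7.26 (0.935), and RPL18, at 13.24 against at most 12.58 (0.85).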

How the results depend on the processing

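Alternatives chosen after the data were seen were the authors' scaling alone, array weights, tumours 2 and 3 as 1 replicate, median centring for the list tests, and leaving out tumours, cell lines or CH22 arrays or giving each comparison 1 notochord specimen for the shared counts, and the planned quantile normalization became the setting reported. Among single genes named in the text, 5515 values kept their side of the threshold, 966 lost their call, 132 gained one and 4 reversed. Among list tests these counts were 1137, 89, 32 and 0. Only values called in the main or the alternative setting could count as reversed. Values that kept their side can therefore include sign changes of values called in neither. Of list medians in fetal spine, 66 moved by less than the spread between specimens, 35 moved by more and 1 reversed. That spread was the SD of the medians against each specimen alone, which were themselves among the alternatives. For these a smaller move was nearly fixed in advance and shows no stability. The reversed values were FGFR2 at -0.87 (tumours against notochord) and -2.03 (cell lines against notochord) with the mean of its probe sets, IDI1 at 1.49 (cell lines against tumours) and BMPR2 at 2.27 (cell lines against notochord) without probe sets that can match several transcripts, and the anterior and central HOX list at -0.0232 in fetal spine against specimen 2 alone. These alternatives read other probe sets or 1 specimen.

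Counts of called genes are given in the order tumours against notochord, cell lines against tumours and cell lines against notochord. Median centring gave 156, 3039 and 4316, with 56 lower in both tumours and lines. The authors' scaling gave 1946 in the second comparison and 16 higher in both. Adding 1 in place of 16 gave 121 and 750 in the first and second comparison, with 29 higher and 51 lower in both. Testing every probe set gave 482, 1998 and 2655, with 89 and 201 shared. Every array as its own replicate gave 1348, 3763 and 4696, with 355 and 439 shared, and counts arrays of 1 specimen or line as independent. Their correlation was 0.792. Fitting only the 2 classes compared gave 149, 720 and 2373, with 18 and 68 shared. Array weights gave 2683, 4582 and 4001, with 622 and 614 shared. Tumours 2 and 3 as 1 replicate gave 53, 518 and 997, with 2 and 40 shared, from fewer units. Leaving out probe sets that can match several transcripts gave 36 higher in both. Camera with an estimated correlation called 0, 0 and 0 lists. The cause was not tested for the scaling, pseudocount, probe set and weighting alternatives.

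With each unit or averaged array left out in turn, counts ran from 15 to 1043, from 28 to 2144 and from 84 to 1562, with 0 to 264 higher and 11 to 333 lower in both. With 1 notochord specimen in each comparison these were 0 higher and 13 or 8 lower. Called lists ran from 17 to 20, from 9 to 12 and from 16 to 20. Where 1 sample of a class was left, it was assumed to vary like the other groups. Between 9.72% and 30.6% of probe sets per array lay under an intensity of 16, where differences are compressed, and without detection calls signal over background is unknown.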

Other observations

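Tests chosen after their results were seen were those of immune cells, of low RNA quality and of scaling over all list members for the macrophage, T cell and MHC class 2 genes, and genes described in the next paragraph outside the naming rule were chosen after their values were seen. The others were set before.

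Genes that set notochord apart from fetal spine differed in how far they were shared by chordoma. FOLR1, a folate receptor gene, was 14.98 ± 0.12 in notochord (SD, n = 2), 10.06 ± 1.01 in tumours (SD, n = 4) and 7.91 ± 0.21 in cell lines (SD, n = 2). Its difference was -4.91 between tumours and notochord (limma adjusted p = 0.0138) and -7.07 between lines and notochord (adjusted p = 0.0037). LYST differed by -1.81 between tumours and notochord (adjusted p = 0.228) and by -5.39 between lines and notochord (adjusted p = 0.0078). The latter call was lost without probe sets that can match several transcripts. YIF1B was 13.47 ± 0.07 in notochord, 12.40 ± 0.66 in tumours and 13.13 ± 0.31 in lines, and neither class was called against notochord. CFTR was 12.14 ± 1.11 in notochord, 9.25 ± 3.39 in tumours and 5.16 ± 0.34 in lines, where the difference of -6.98 was called (adjusted p = 0.0483).

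The cell lines differed from each other in cartilage genes, which was not tested. COL2A1 was 7.30 and 7.71 on the CH22 arrays and 12.16 in UCH1, COL11A1 was 5.53 and 5.64 against 9.71, and SOX6 was 5.98 and 7.20 against 8.91. HAPLN1 was 12.88 and 13.10 in CH22 and 14.70 in UCH1. SHH was 9.05 and 9.06 in CH22 and 11.94 in UCH1. HBB, a globin of red cells, was 15.67 in tumour 1, 8.98 in tumour 2, 9.93 in tumour 3 and 15.14 in tumour 4, against 10.12 to 12.17 on the notochord arrays.

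Muscle, marrow and cartilage markers were higher on notochord arrays than in tumours. A candidate explanation is tissue around the notochord in the captured material. Over the skeletal muscle markers the median of notochord minus fetal spine was -2.63, and -1.05 and -4.13 in the specimens, so muscle transcripts were present in both, and MYH3 was 13.14 to 15.08 on the notochord arrays and 15.96 in fetal spine. Low RNA quality cannot be told apart for these genes. In tumour 1, whose actin ratio lies in the notochord range, they differed from the other tumours by a pooled median of 0.859. That lies between the bounds set for the test, but the lists differed, at 2.28 for muscle, 0.92 for marrow and 0.34 for cartilage markers. Marrow markers were higher in notochord than in fetal spine by medians of 5.26 and 4.14, and cartilage markers by 1.72 and 2.32. The spine array is therefore no reference for those parts, and a difference of the notochord itself stays open and untested.

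Macrophage, T cell and MHC class 2 lists were higher in tumours than on notochord arrays, called by camera with a preset correlation but not with an estimated one (adjusted p = 0.270, 0.211 and 0.203), and the first 2 not with fry (0.100 and 0.0569). Scaling between arrays as the whole cause is argued against for these genes, since it moves genes of like intensity alike. The median over all 34 members exceeded that of random lists of like intensity by 3.05, at 3.02 against at most 1.07 in 10000 lists. It was 2.53 against 0.59 under the authors' scaling and 3.24 against 1.30 after median centring. Those scalings differ only by a constant for each array, so both gave an excess of 2.80 and are not separate checks. The median also lay above the highest of the random lists without each tumour or specimen. The lists were taken up because they were higher and their genes vary together, so the random lists say nothing about chance. That 8 of 8 called members stayed positive under the authors' scaling decides nothing, because they were chosen by size, and CD14, CD3G and HLA-DPA1 lost their call there, moving from 3.67 (SE 0.77), 3.65 (SE 0.75) and 4.48 (SE 0.95) to 2.86 (SE 0.77), 2.89 (SE 0.76) and 4.11 (SE 1.05). Immune cells in the resected tumours may account for the pattern. Macrophage markers differed by -5.26 between cell lines and tumours, but lines hold no such cells and were lower than notochord too, with a median of -3.07. That contrast therefore shows only that the lines express little of these genes and does not decide the question. CD163 was 12.11 in tumours and 8.12 in notochord, although LYZ, which marrow cells also express, was 13.09 and 13.02. Low RNA quality may account for a part as well, since the macrophage markers differed by -2.54 between tumour 1 and the other tumours, so both stay open, and a biological difference between chordoma and notochord cells was not tested.

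The calls were compared with other splits of the units. Between tumours and notochord the real split gave 285 genes and the highest of the other splits 8, and 1 of 15 splits gave as many. Between cell lines and tumours these were 1291, 0 and 1 of 15. With 15 splits no share under 0.05 can be reached.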
